A study of Mus musculus with 19 samples.

How the data were processed

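Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase inserts adapters into open DNA, in Prom1-positive cells separated with magnetic beads from mouse forebrain at embryonic day 14. The 19 libraries fall into 4 groups: 4 controls, 4 Foxc1 mutants, 5 controls on a retinoic acid diet and 6 mutants on that diet. The mutant genotype joins the hith allele of Foxc1, which is hypomorphic, with a LacZ insertion allele. Groups were taken from the sample titles. Mutant 1 carries a wild-type genotype label that conflicts with its title, so summit numbers, near-end shares, separated regions with their checks, limma and camera results were also computed without it. The labels do not say whether libraries of a group come from separate animals, so p-values measure only the spread between these samples. They name no preparation batch, date or sex.

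The deposited files list peak summits that the authors called with MACS2 on each library alone, without scaling between libraries. Per summit, the score deposited by the authors is a -log10 q value (neg_log10_p) that MACS2 computed against the local background of that library. The smallest deposited score of each library was near 1.30, the value that a q of 0.05 gives. The authors' processing notes also name BWA, Signac and DiffBind and the mouse builds mm10 and GRCm38, without versions. Read counts and peak widths were not used here, so sequencing depth is unknown, and the number of summits per library (29112 to 122591) stands in for it. No interval that needs a read count was computed. Scores were used untransformed, to rank the summits within a library and, as the median per library, as a covariate and a measure to compare libraries.

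Because the number of summits differed between libraries, each was reduced to its 29112 best-scoring summits, the length of the shortest list (mutant 4 on the diet). This matched set equalises list length, not sensitivity: a gene or region without a matched summit can still have a weaker one. Genes and coordinates came from a table of GRCm38.p6 with 21887 protein-coding genes, on chromosomes 1 to 19, X and Y. That table has no strand, so the planned use of transcription start sites was replaced by the nearer of both ends of a gene. Each summit was assigned to the protein-coding gene with the nearest end within 100 kb. The share of summits within 1 kb of a gene end replaced the planned share at start sites. The planned motif shares need a genome sequence and were not computed.

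Regions were made by chaining matched summits at most 200 bp apart and keeping regions with summits from at least 2 libraries. Per region, presence was compared between groups with a two-sided Fisher's exact test. Genotype was also tested within diet, and diet within genotype, by an exact test stratified on the other factor. Regions with a summit in each library of 1 group and in no library of the other are called separated below. Each set of separated regions was then scored in the 2 groups that took no part in defining it, as the percentage of its regions with a summit per library, by a two-sided exact permutation test adjusted over 6 sets. Separated regions and that check were added after the data were examined.

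Summits per gene were analysed for 10828 genes with a mean of at least 1 summit over the libraries. Values were log2 of summits plus 0.5, fitted with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3 with 1 coefficient per group. Of these genes, 3259 had the same count in all libraries of each group, which leaves no residual variance, so limma offset their variances from zero. Among them 3258 were alike in all libraries, and Fgfbp3 was the 1 that differed between groups. Its SE and p-values therefore rest on the variance that limma borrows from other genes. Etaa1, Rad51c and Pdcd1 also had no spread within either group of the contrasts that called them. Their spread came from another group (SD 0.5), so their p-values carry a similar limit. All contrasts share this estimate, so leaving out a library outside a contrast can end or make a call there. Whether the genes alike in all libraries, which stayed in the fit, lowered the borrowed variance was not tested. Contrasts were mutant against control, each genotype on against off the diet, mutants on the diet against controls and against controls on the diet, and the interaction of genotype and diet. Gene lists were tested with camera at a correlation of 0.01, and again with the correlation estimated for each list. A list needed more than 2 measured genes for camera. The 18 lists cover retinoic acid signalling, Hox genes, Notch, radial glia and neural stem cells, intermediate progenitors, projection neurons, ganglionic eminence and interneurons, cell cycle, cortical hem and choroid plexus, Wnt and BMP, Hedgehog, gliogenesis, endothelial, mural, meningeal fibroblast, microglia and macrophage, erythroid and housekeeping genes. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the other steps.

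The groups, contrasts, gene lists, tests, alternatives and the rule for named items were set before the data were examined, apart from the changes stated here. The rule names up to 10 genes per direction and contrast past the threshold or, where none passes, the 3 per direction with the smallest p. It adds 22 focal genes in the mutant against control and the mutant diet contrasts, of which 21 passed the filter (Cyp26b1 did not). It also names members of lists past the threshold and up to 5 regions per direction with the smallest exact p. Other genes and regions named in the text, such as those passing when adjusted over their list alone, were chosen after their values were seen. Some genes that these rules select are not reported here. Alternatives covered the number of summits kept, region width, gene assignment, pseudocount, filter, list length as covariate, a replicate block, sex chromosomes and leaving out each library. Replicate numbers did not pair the libraries: of 25 pairs sharing a number, 3 had a residual correlation above 0.1 (range -0.209 to 0.143).

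The procedures were tested on simulated data. Summits per gene were drawn for each library independently at the occupancy pooled over all libraries, so differences between libraries of a group were left out. Only genes with a mean of at least 2 summits were altered, so the rates do not cover genes with fewer. With 50 genes altered per step, limma recovered 56% of genes raised 2-fold and 32% of genes lowered 2-fold for mutant against control, and 92% and 62% at 3-fold. Over the 5 contrasts the range was 56 to 74% raised and 18 to 40% lowered at 2-fold, and 92 to 96% and 32 to 64% at 3-fold, lowest for lowered genes between mutants on and off the diet. In these runs, with 200 genes altered at once, it also called 2 to 13 unchanged genes per contrast. The threshold allows some such calls beside many true ones. They therefore give no rate of false calls for the real contrasts, where 0 to 3 genes were called. The camera test found the altered list in each of the 5 contrasts. Fisher's exact test recovered 0 of 200 fully separated regions at these group sizes, so its counts of 0 say little, whereas the stratified test recovered 200 of 200 altered at once. Where only a few regions are fully separated, they can fail the stratified test too, as Lix1 and Sall1 did in the real libraries.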

Results

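Open chromatin was profiled by ATAC-seq in 19 libraries of Prom1-positive forebrain cells from mouse embryos at embryonic day 14. Prom1 is a surface protein of neural progenitors. The series asks how retinoic acid from the meninges, the membranes around the brain, acts on neurogenesis through Notch and Sox2. Foxc1, which is needed for forebrain meninges to form, was mutated, and retinoic acid was given in the diet. The groups were 4 controls, 4 mutants, 5 controls on the diet and 6 mutants on the diet, with 1547369 deposited summits in all. Controls had 98555 ± 22068 summits (SD, n = 4) and mutants 95379 ± 30545 (SD, n = 4). Controls on the diet had 77804 ± 13693 (SD, n = 5) and mutants on the diet 63769 ± 23749 (SD, n = 6). In the 5 contrasts between groups, this number did not pass two-sided exact permutation tests (exact p = 0.0667 to 0.857, lowest adjusted p = 0.265). Without mutant 4, the difference of mutants on the diet from mutants was -46802 summits (exact permutation p = 0.0238, adjusted p = 0.0476). Without control 2, their difference from controls was -41773 (exact permutation p = 0.0476, adjusted p = 0.134). Comparisons below use the 29112 best-scoring summits of each library, so presence means presence among these.

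**Figure D1:**
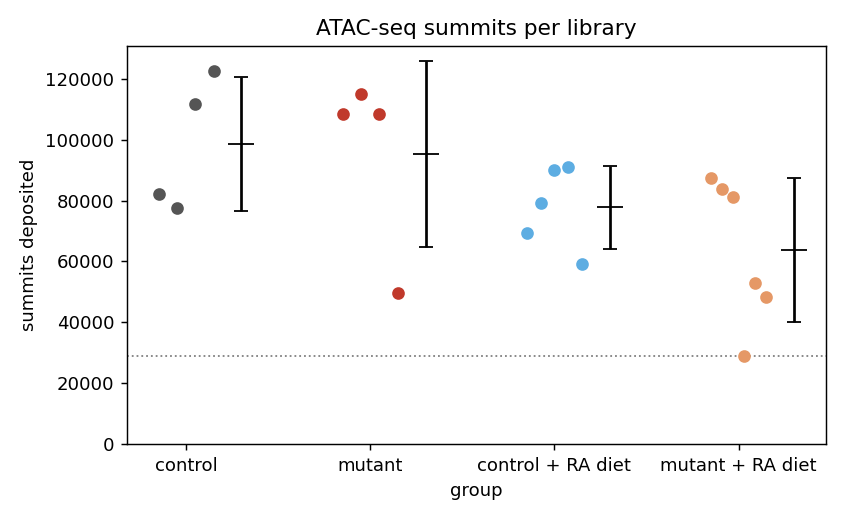
Deposited ATAC-seq summits per library (vertical axis) for the 4 groups (horizontal axis), where points are libraries, bars are means with SD, and the dotted line is the shortest list of 29112 summits. Mutant 4, with 49804 summits, lies below the other mutants.

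Many genes of cycling neural progenitors were open at their ends in all 19 libraries. Sox2, Sox1, Sox3 and Sox9, transcription factors of neural stem cells, had a summit within 1 kb of a gene end in each library, as did Fabp7, Slc1a3, Vim, Hopx, Emx1 and Emx2. That held for 17 of 28 genes of the radial glia and neural stem cell list, 17 of 25 of the cell cycle list (Mki67, Cdk1, Pcna and Top2a among them) and 8 of 15 of the intermediate progenitor list (Neurog1, Neurod1 and Btg2 among them). In the Notch list it held for 14 of 27 genes, including the receptor gene Notch2, the ligand gene Dll1 and the target genes Hes5 and Hey1. The share among all 21887 protein-coding genes was 36.6% (8003 genes).

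Lists of other cell types had few such genes. In the meningeal fibroblast, erythroid and Hox lists it held for 0 of 15, 0 of 12 and 0 of 15 genes, and 14 of the Hox genes, which pattern the hindbrain and spinal cord, had no such summit in any library. The endothelial, mural and microglia lists had 1 each (Kdr of 15, Tbx18 of 10 and Irf8 of 14). Retinoic acid signalling had 2 of 23 (Aldh1a3 and Meis1), while the receptor genes Rara and Rarb, the binding-protein genes Crabp1 and Crabp2 and the degrading-enzyme genes Cyp26a1 and Cyp26b1 had no such summit in any library. Between these stood Wnt and BMP with 11 of 22, Hedgehog with 5 of 12, projection neuron with 9 of 25, gliogenesis with 3 of 13, cortical hem and choroid plexus with 3 of 18, and ganglionic eminence and interneuron with 3 of 23. Housekeeping had 11 of 15. These counts were not tested against each other. Genes without a summit at an end can have distal ones: Pax6, a radial glia transcription factor, had an end summit in 1 library but 13 assigned regions, 5 of them in all libraries.

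**Figure D2:**
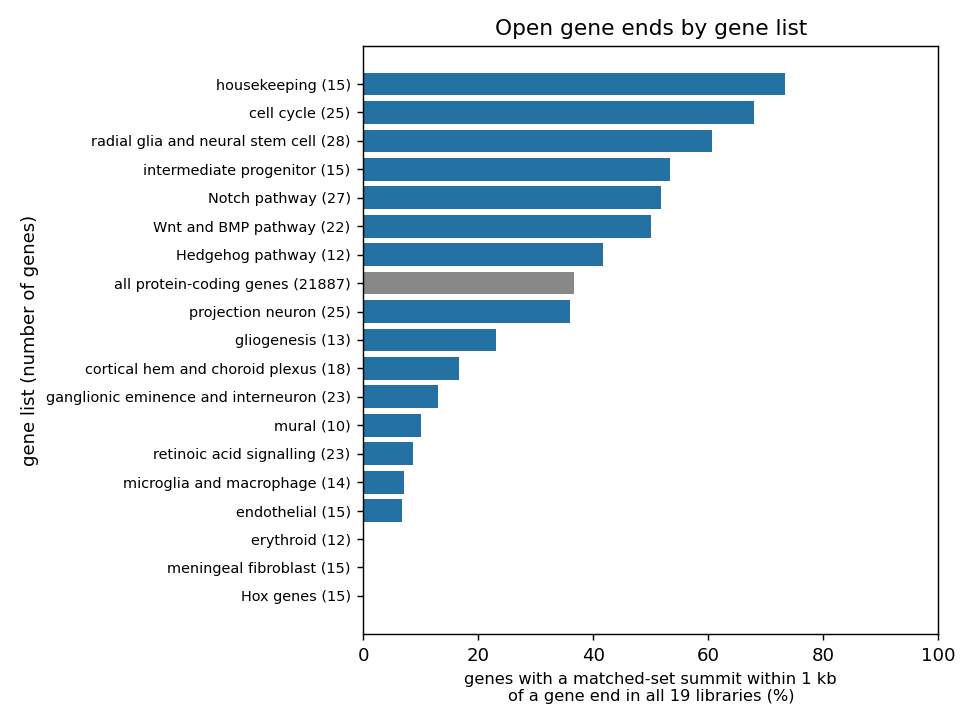
Percentage of the genes of each list (number of genes in parentheses, vertical axis) with a matched-set summit within 1 kb of a gene end in all 19 libraries (horizontal axis, %). Cell cycle and radial glia lists lie above the 36.6% of all protein-coding genes (grey), and meningeal fibroblast, erythroid and Hox lists lie at 0.

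Matched summits formed 44878 regions, of which 13035 (29.0%) held a summit of every library. Of those shared by all libraries, 48.5% lay within 1 kb of a gene end, against 17.1% of the rest. The share of matched summits near a gene end did not differ by test between groups. It was 32.2% ± 1.64 in controls (SD, n = 4) and 32.4% ± 1.68 in mutants (SD, n = 4). It was 32.5% ± 0.491 in controls on the diet (SD, n = 5) and 31.9% ± 2.23 in mutants on the diet (SD, n = 6), with two-sided exact permutation p-values from 0.665 to 0.905. Without mutant 6 on the diet, whose share was 36.2%, mutants on the diet were lower than controls on the diet by a change of -1.40 points (exact permutation p = 0.0159, adjusted p = 0.0476).

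Mutants against controls asks whether mutation of Foxc1, a gene needed for the meninges to form, alters progenitor chromatin. Meningeal retinoic acid was not measured here. The genes of the Notch pathway and Sox2 had no change past the threshold. Sox2 had 7.75 ± 2.22 assigned summits in mutants and 6.5 ± 1.29 in controls (SD, n = 4 each), a log2 difference of 0.21. The Notch receptor gene Notch2 had 8.25 ± 1.89 against 6.5 ± 1.29 (log2 0.32). The Notch target gene Hes1 had 7.25 ± 2.06 against 5.5 ± 1.29 (log2 0.35), and Hes5 had 4.75 ± 0.50 against 4.25 ± 0.50 (log2 0.14). The Notch ligand gene Jag1 had 5.25 ± 1.5 against 3.75 ± 0.50 (log2 0.41 with SE 0.18, limma adjusted p = 0.793). Among these 8 libraries its 2 highest counts, 6 and 7, were in mutants 3 and 4, as were those of Sox2 (10 and 9), Hes1 (9 and 9) and Notch2 (11 and 8, the latter shared with control 2). Mutants 1 and 2 had 5 and 7 for Sox2, 6 and 5 for Hes1 and 7 and 7 for Notch2, within the range of controls.

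Of all 10828 genes, limma called 0 between mutants and controls. At an unadjusted p under 0.05 there were 619 genes, 220 with more and 399 with fewer summits in mutants. The smallest p-values with more summits belonged to Etaa1, an activator of the ATR checkpoint kinase, Lef1, a transcription factor of Wnt signalling, and Cdh11, a cadherin. Lef1 had 4.25 ± 1.71 summits in mutants and 1.25 ± 0.50 in controls (SD, n = 4 each), a log2 difference of 1.39 with SE 0.32 (limma adjusted p = 0.602), and 3 of 4 mutants lay above the highest control. With fewer summits the smallest p-values belonged to Rabif, the chromatin remodelling subunit gene Actl6a and the splicing factor gene Prpf40b (log2 -0.86, -0.55 and -0.55, limma adjusted p = 0.390 each). The remaining focal genes, among them the neurogenic Neurog2 (log2 0.21), Eomes (-0.09) and Tbr1 (0.47), Pax6 (0.16), Rbpj (0.33), Dll1 (0.07), Hey1 (0.12), Notch1 (-0.02), Rarb (0.31), Rara (0.00) and Foxc1 itself (0.37), had limma adjusted p-values of 0.793 or above.

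By list, camera called 0 of the lists between mutants and controls, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.263. Those were the meningeal fibroblast list, with 5 of 8 measured genes higher (median log2 0.32, p = 0.0285, and p = 0.0387 with an estimated correlation), and the cortical hem and choroid plexus list, with 11 of 14 lower (median log2 -0.21, p = 0.0378, and p = 0.135 with an estimated correlation). Retinoic acid signalling had 9 of 16 genes higher and 5 lower (median log2 0.21, camera adjusted p = 0.263). Notch had 10 of 24 genes higher and 9 lower, with a median of 0.00 and a mean of -0.04, while camera ranked it up (camera adjusted p = 0.467). Radial glia had 15 of 27 genes higher (camera adjusted p = 0.467) and intermediate progenitor 8 of 15 lower (camera adjusted p = 0.806). Hedgehog had 6 of 11 higher (camera adjusted p = 0.263), gliogenesis 7 of 11 lower (camera adjusted p = 0.263) and endothelial 5 of 8 lower (camera adjusted p = 0.430). The camera adjusted p was 0.430 for ganglionic eminence, 0.448 for housekeeping, 0.467 for microglia, 0.784 for cell cycle, 0.806 for Wnt and BMP and 0.950 for projection neuron genes. Hox, mural and erythroid lists had 1, 1 and 2 measured genes and were not tested. Adjusted over the list alone, 3 genes passed: Lef1 in the Wnt and BMP list, and the ventral forebrain transcription factor genes Olig1 (log2 0.86) and Lhx8 (log2 -0.86) in the ganglionic eminence list, against 0 over all genes.

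**Figure D3:**
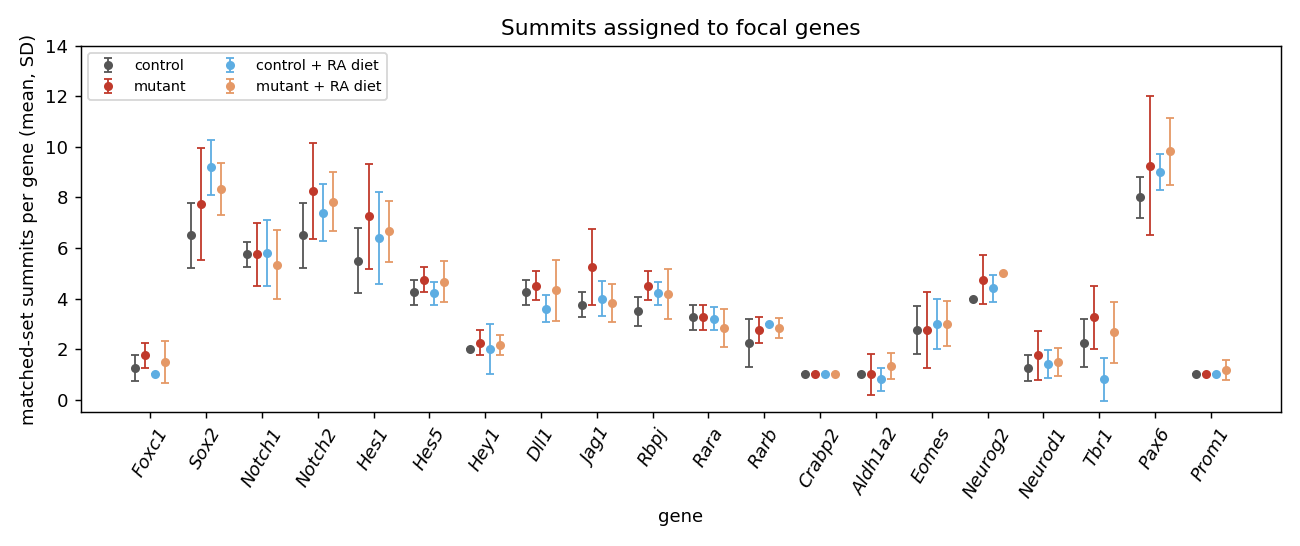
Matched-set summits assigned to focal genes (vertical axis, summits per gene) in the 4 groups, where points are group means and bars SD over 4, 4, 5 and 6 libraries. The SD bars of Sox2 and the Notch genes overlap between mutants and controls, while those of Sox2 in controls on and off the diet do not overlap.

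Among regions, 45 had a summit in all 4 controls and in no mutant, and 23 the reverse. Genes of the lists next to the 45 regions were Lhx8, the retinoic acid-linked homeobox gene Meis2 and the proneural gene Neurod4. No list was enriched next to separated regions in the 6 of 10 sets tested, those with at least 20 regions within 100 kb of a gene end (108 Fisher's exact tests, 1 at an unadjusted p under 0.05, lowest adjusted p of 1). At Pfkfb3, a regulator of glycolysis, a region inside the gene at chromosome 2, 11502003 to 11502151 (mm10), was present in 4 of 4 controls and 0 of 4 mutants, and a neighbouring one at 11501397 to 11501594 had the reverse. A paired shift of this kind also stood at the histone gene H1f2. Fisher's exact test called 0 regions (68 at an unadjusted p under 0.05), and exact p = 0.0286 is the smallest that 4 against 4 libraries allow. Of the missing library and region combinations, 53.3% for the 45 and 69.6% for the 23 regions had a deposited summit below the matched set. A deposited summit of any rank lay within 1 kb of the region in 85.0% and 98.9%.

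The 45 regions absent in mutants were then read in libraries that had not defined them. Mutants on the diet had a summit in 32.6% ± 5.38 of them (SD, n = 6) and controls on the diet in 45.3% ± 6.59 (SD, n = 5), a difference of -12.7 points (two-sided exact permutation p = 0.0130, adjusted p = 0.0260 over 6 sets). For the 23 regions present only in mutants the values were 43.5% ± 12.9 and 47.0% ± 8.36 (exact permutation p = 0.634). Without mutant 1, whose genotype label says wild type, limma again called 0 genes, 203 regions were separated and the difference was -13.8 (exact permutation p = 0.0173). The difference over the 45 regions did not pass without control 2 (-8.32, exact permutation p = 0.0671), without mutant 3 (-9.37, exact permutation p = 0.0519), with all deposited summits (-11.2, exact permutation p = 0.275) or with 14556 per library (-7.67, exact permutation p = 0.234).

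Controls on against off the diet asks what supplied retinoic acid does without the mutation. Sox2 had 9.20 ± 1.10 summits on the diet (SD, n = 5) against 6.5 ± 1.29 (SD, n = 4), which did not pass limma. Of all genes limma called 0 (461 at an unadjusted p under 0.05), and Rad51c, a gene of homologous recombination, came closest with 1 summit in each of 5 libraries on the diet and 2 in each of 4 controls (log2 -0.74 with SE 0.11, adjusted p = 0.0558). It passed without mutant 2, a library outside this contrast (limma adjusted p = 5.42e-04). It also passed with no filter (0.0321) and without the robust step (0.0289), the latter chosen after seeing the data. Rabif and the SUMO protease gene Senp1 followed with fewer summits (log2 -0.86 and -0.75), and Mos, Asb13 and Zfp62 with more (log2 0.74 each, limma adjusted p = 0.206, 0.350 and 0.350).

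The retinoic acid signalling list held 54.8 ± 1.10 matched summits per library on the diet (SD, n = 5) and 50.3 ± 1.26 in controls (SD, n = 4), with each diet library above each control (two-sided exact permutation p = 0.00794, the smallest possible, adjusted p = 0.143 over the lists). Mutants held 57.0 ± 5.48 (SD, n = 4, against controls exact permutation p = 0.143, with mutant 2 at 49), and 54.2 ± 6.34 on the diet (SD, n = 6), a diet difference of -2.83 (exact permutation p = 0.486). Gliogenesis and mural lists had fewer summits in controls on the diet (exact permutation p = 0.0317 and 0.0476, adjusted p = 0.286 for both), as mural had in mutants against controls (exact permutation p = 0.0286, adjusted p = 0.514). By camera, 9 of the 16 measured retinoic acid signalling genes were higher in controls on the diet (median log2 0.04, camera adjusted p = 0.174). Camera called 0 lists with 4 at an unadjusted p under 0.05, and the lowest adjusted p, 0.170, was shared by the meningeal fibroblast, Hedgehog and ganglionic eminence lists. With an estimated correlation, camera adjusted p-values were 0.253, 0.253 and 0.286, and 0.410 for Wnt and BMP, the fourth list. Hhip, Ptch1 and Gli1, target genes of Hedgehog signalling, led the Hedgehog list, where 6 of 11 genes were higher. Adjusted over the list alone, 1 gene passed, Olig1 with 4.80 ± 0.45 against 2.5 ± 0.58 summits (SD, n = 5 and 4, log2 0.84). Leaving out control 1 or control 1 on the diet gave 1 list past the threshold, Hedgehog (camera adjusted p = 0.0302) and Wnt and BMP (camera adjusted p = 0.0487).

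Among regions, 100 had a summit in all 5 controls on the diet and in no control, and 80 the reverse. List genes next to the 100 were the FGF receptor gene Fgfr2, Foxp2 and the Notch coactivator gene Maml3, and those next to the 80 were Foxc2, Neurod4 and the gliogenic gene Nfia. Present in 5 of 5 on the diet and 0 of 4 off it were regions near the endothelin gene Edn2 (chromosome 4, 120190123 to 120190184), in Ripor2 (chromosome 13, 24565950 to 24566054) and in Pfkfb3. The reverse held in Arhgef28 and Fam222a. It also held for a neighbouring region in Pfkfb3 (chromosome 2, 11502003 to 11502151), so there the summit shifted within the gene. Regions in 1110051M20Rik formed another such pair. Fisher's exact test called 0 regions (1176 at an unadjusted p under 0.05, smallest possible exact p = 0.00794). Of the missing library and region combinations, 78.5% for the 100 and 56.0% for the 80 regions had a deposited summit below the matched set. The 80 were looked up in libraries on the diet, whose lists were shorter on average, which alone can lower such a percentage. A deposited summit of any rank lay within 1 kb of the region in 98.0% and 87.5%. Much of this separation is thus one of rank or summit position. The 100 regions had a summit in 70.2% ± 22.3 of cases in mutants on the diet (SD, n = 6) and 41.8% ± 26.3 in mutants (SD, n = 4), exact permutation p = 0.110. The 80 regions had one in 18.8% ± 9.62 and 45.0% ± 34.3, exact permutation p = 0.105. Mutants 3 and 4 had 64% and 65% of the 100 regions and mutants 1 and 2 had 18% and 20%.

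Mutants on against off the diet asks whether supplied retinoic acid alters chromatin in mutants, whose meningeal source of it was not measured here. Fgfbp3, the gene of a protein that binds fibroblast growth factors, rose from 1 summit in each of 4 mutants to 2 in each of 6 mutants on the diet (log2 0.74 with SE 0.03, limma adjusted p = 7.56e-11). It was the 1 gene among 3259 without spread inside any group whose count differed between groups, so this p comes from borrowed variance and overstates what 4 against 6 counts can show. Etaa1 fell from 3 summits in each mutant to 2 in each mutant on the diet (log2 -0.49 with SE 0.07, limma adjusted p = 0.0242). These were the 2 genes called, with 738 at an unadjusted p under 0.05. Sox2 had 8.33 ± 1.03 summits on the diet (SD, n = 6) against 7.75 ± 2.22 (SD, n = 4), and Jag1 had 3.83 ± 0.75 against 5.25 ± 1.5 (log2 -0.39, limma adjusted p = 0.659). The other focal genes had log2 differences from -0.26 for Tbr1 to 0.46 for Aldh1a2, a gene of retinoic acid synthesis, and none passed.

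The Fgfbp3 region (chromosome 19, 36910811 to 36910912) had deposited summits in 10 of the 13 libraries outside mutants on the diet, all ranked below the matched set, and Fgfbp3 was not called without mutant 1 (limma adjusted p = 0.127) or with the shortest list left out (log2 0.44, adjusted p = 0.635). With gene bodies and 5 kb on both sides, Fgfbp3 had a log2 difference of 0.00 (limma adjusted p = 1) in each of the 4 contrasts that otherwise called it, and so had Etaa1 here. For Fgfbp3 the window fixed this result, since the region lies 6689 bp from the gene end and is not counted. Etaa1 had a limma adjusted p of 0.05 or more in 15 of 19 fits that left out 1 library, reaching 0.578. The 15 were those without any of the 4 controls or 4 mutants, without controls 1, 3, 4 or 5 on the diet, or without mutants 2, 3 or 4 on the diet. The direction of Etaa1 turned with the shortest list left out (log2 0.33). With all deposited summits, scaled by list length, it was log2 0.24. Mean log2 list length differed by -0.607 in this contrast, which raises scaled counts on the diet, so the 0.24 alone shows no reversal. By list, camera called 0, with 1 at an unadjusted p under 0.05: 7 of 8 endothelial genes were higher (median log2 0.19, p = 0.0227, adjusted p = 0.341, and p = 0.0527 with an estimated correlation). Retinoic acid signalling had 6 of 16 genes higher and 9 lower and Notch 7 of 24 higher and 14 lower (median log2 -0.04, mean 0.05, camera adjusted p = 0.832 for both). Adjusted over the list alone, 1 gene passed, the BMP receptor gene Bmpr1a, with 1.17 ± 0.41 summits on the diet (SD, n = 6) against 2.5 ± 0.58 (SD, n = 4), log2 -0.86.

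Regions present in all 6 mutants on the diet and in no mutant numbered 24, and the reverse 30, among them regions near Bmpr1a and Meis2. Dab1, an adaptor of Reelin signalling, held a region at chromosome 4, 104270307 to 104270364 in 6 of 6 mutants on the diet and 0 of 4 mutants, and Get4 and Dok5 held regions with the reverse. Of the missing library and region combinations, 52.1% for the 24 and 32.2% for the 30 regions had a deposited summit below the matched set. The 30 were looked up in libraries on the diet, whose lists were shorter on average, which alone can lower such a percentage. A deposited summit of any rank lay within 1 kb of the region in 86.5% and 67.8%. Both sets were found at different rates in control libraries that had not defined them. The 24 regions had a summit in 71.7% ± 8.01 of cases in controls on the diet (SD, n = 5) and 34.4% ± 19.9 in controls (SD, n = 4), a difference of 37.3 points. The 30 regions had one in 30.0% ± 3.33 and 55.0% ± 15.5, a difference of -25.0 points (two-sided exact permutation p = 0.00794 each, the smallest possible, adjusted p = 0.0238). All 5 controls on the diet lay above all 4 controls in the first set and below them in the second. The first difference did not pass without mutant 2 (23.3, exact permutation p = 0.0556) or mutant 3 (38.3, exact permutation p = 0.0556), and the second did not with all deposited summits (-30.2, exact permutation p = 0.0873) or the shortest list left out (-19.6, exact permutation p = 0.0635). Without mutant 2 it was -14.8 (exact permutation p = 0.00794).

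**Figure D4:**
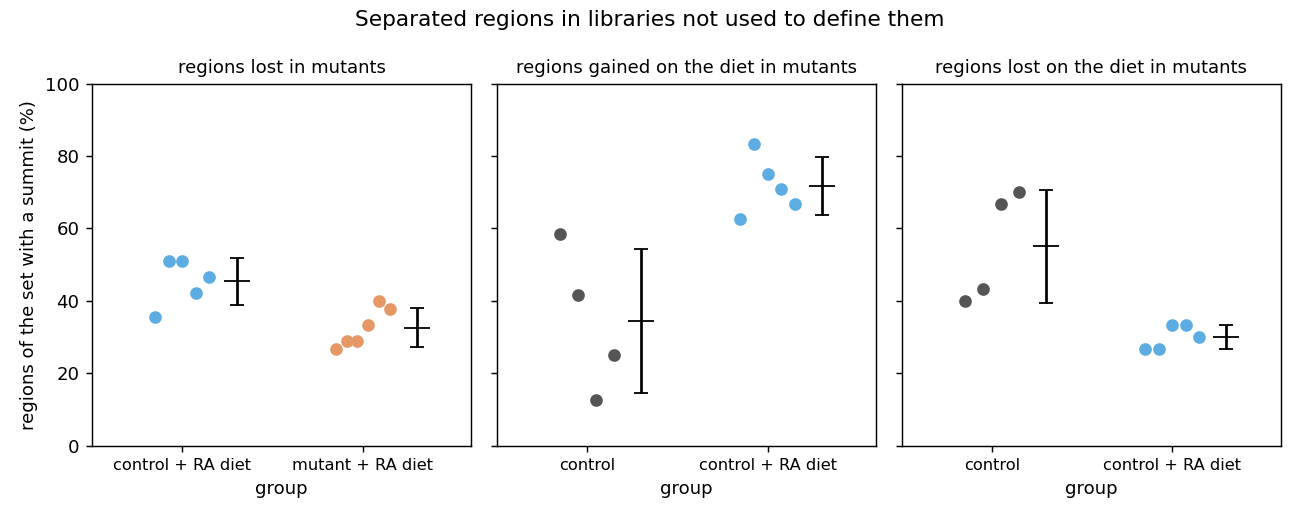
Percentage of the regions of a set with a matched-set summit per library (vertical axis) in the 2 groups that did not define the set (horizontal axis), where points are libraries and bars are means with SD. Regions absent in mutants were less often occupied in mutants on the diet than in controls on the diet, and the sets gained and lost on the diet in mutants split the controls by diet.

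Across both genotypes, the exact test of diet stratified by genotype called 0 regions, with 1864 at an unadjusted p under 0.05 and a lowest adjusted p of 0.779. A region inside Lix1 (chromosome 17, 17409168 to 17409287) was present in all 11 libraries on the diet and in none of the 8 off it (exact p = 3.78e-05, the smallest possible). A region near Sall1, a zinc finger transcription factor gene (chromosome 8, 89073066 to 89073212), was present in all 8 off the diet and in none on it, with the same exact p. Part of both differences is one of rank: at Lix1, 4 of 4 controls and 1 of 4 mutants had a deposited summit outside the matched set, and at Sall1, 2 of 5 controls and 3 of 6 mutants on the diet had one. The other libraries without a matched summit had no deposited one. Regions near the glutamate receptor gene Grik3 and the cannabinoid receptor gene Cnr1 were next among those gained, and one near the receptor tyrosine kinase gene Kit among those lost.

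Mutants on the diet against controls asks how far mutants given retinoic acid differ from the reference state. Fgfbp3 rose from 1 summit in each of 4 controls to 2 in each of 6 libraries (limma adjusted p = 7.56e-11, but log2 0.07 and adjusted p = 1 with the shortest list left out). Rad51c and Pdcd1, the gene of an immune checkpoint receptor, fell from 2 summits in each control to 1 in each mutant on the diet (log2 -0.74 with SE 0.11, limma adjusted p = 0.0123 for both). These 3 genes were called, with 723 at an unadjusted p under 0.05. Rad51c and Pdcd1 each had a limma adjusted p of 0.05 or more in 12 of 19 fits that left out 1 library (up to 0.293 and 0.330): for both, those without any control, mutant 1, controls 1, 3, 4 or 5 on the diet or mutants 2 or 3 on the diet, and further mutant 4 for Rad51c and mutant 2 for Pdcd1. Without mutant 6 on the diet the count was 13, including these 3. None of the genes called in any contrast was called with all deposited summits, with 14556 or with 48323 summits per library.

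Adjusted over the list alone, 7 genes passed between mutants on the diet and controls, against 0 over all genes: Lef1 (log2 1.05), Olig1 (0.70) and Dcn (0.61) with more summits, and Bmpr1a (-0.98), Ccnd2 (-0.87), Olig2 (-1.38) and Stra6 (-1.0) with fewer. Stra6 is a receptor for vitamin A uptake and Ccnd2 a cyclin of progenitors. By camera 0 lists passed, with 1 at an unadjusted p under 0.05, meningeal fibroblast, where 6 of 8 genes were higher (median log2 0.19, p = 0.00824, adjusted p = 0.124, and p = 0.0154 with an estimated correlation). Of the regions, 55 were present in all 6 mutants on the diet and in no control, and 120 the reverse. The proneural gene Neurog2 held 1 of the 55 (chromosome 3, 127634228 to 127634333, in 3 of 4 mutants and 3 of 5 controls on the diet), and the Hedgehog effector gene Gli3 lay next to another. Fisher's exact test called 0 regions (1235 at an unadjusted p under 0.05, smallest possible exact p = 0.00476). Of the missing library and region combinations, 74.5% for the 55 and 38.2% for the 120 regions had a deposited summit below the matched set. The 120 were looked up in mutants on the diet, whose lists were shorter on average (63769 against 98555 summits). Shorter lists alone can lower such a percentage. A deposited summit of any rank lay within 1 kb of the region in 93.6% and 66.5%.

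Mutants against controls, both on the diet, asks whether genotype matters once retinoic acid is supplied. Bmpr1a fell, with 1.17 ± 0.41 summits in mutants on the diet (SD, n = 6) against 2.80 ± 0.45 (SD, n = 5), log2 -1.0 with SE 0.16 (limma adjusted p = 0.0320). Pdcd1 fell from 2 summits in each of 5 controls on the diet to 1 in each of 6 mutants on the diet (limma adjusted p = 0.00833), and Fgfbp3 rose from 1 to 2 (limma adjusted p = 2.77e-11). These 3 genes were called, with 330 at an unadjusted p under 0.05. A region inside Bmpr1a (chromosome 14, 34453901 to 34454042) was present in 0 of 6 mutants on the diet and in all 13 other libraries, although 4 of the 6 had a deposited summit there below the matched set. Bmpr1a had a limma adjusted p of 0.05 or more in 13 and Pdcd1 in 11 of 19 fits that left out 1 library (up to 0.176 and 0.265), and with all deposited summits, scaled by list length, the log2 difference of Bmpr1a was -0.37 (adjusted p = 0.859). For both genes these included the fits without controls 1, 2 or 4, mutant 1, controls 3, 4 or 5 on the diet, or mutants 2 or 3 on the diet. Leaving out control 3 and control 1 on the diet ended the call for Pdcd1 alone, and leaving out control 2 on the diet and mutants 1, 4 or 6 on the diet for Bmpr1a alone.

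Vcan, the gene of the matrix proteoglycan versican, held a region at chromosome 13, 89739430 to 89739598 in 6 of 6 mutants on the diet, 1 of 4 mutants and 0 of 9 controls on and off the diet. In all, 4 regions were present in each mutant on the diet and in no control on the diet, and 4 the reverse, near Pdcd1, Atxn1, Sorl1 and Bmpr1a. Fisher's exact test called 0 regions (137 at an unadjusted p under 0.05, smallest possible exact p = 0.00216). By camera 0 lists passed, with 1 at an unadjusted p under 0.05: all 4 measured microglia genes were lower (median log2 -0.14, p = 0.0126, adjusted p = 0.189, and p = 0.0962 with an estimated correlation). Adjusted over the list alone, Bmpr1a, the neuronal transcription factor gene Tbr1 (log2 1.49, 2.67 ± 1.21 against 0.80 ± 0.84 summits) and the leukocyte gene Ptprc (log2 -0.32) passed. The exact test of genotype stratified by diet called 0 regions, with 751 at an unadjusted p under 0.05.

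The interaction asks whether the diet acted differently in mutants. Fgfbp3 was the 1 gene called (log2 0.74 with SE 0.04, limma adjusted p = 2.26e-08), with 378 at an unadjusted p under 0.05. Its limma adjusted p was 0.05 or more in 13 of 19 fits that left out 1 library, up to 1, namely without any control, mutants 1, 2 or 4, controls 1, 3, 4 or 5 on the diet, or mutants 2 or 3 on the diet. Adjusted over the list alone, Bmpr1a passed (log2 -0.88). By camera 0 lists passed, with 2 at an unadjusted p under 0.05, Hedgehog (median log2 -0.07) and retinoic acid signalling, where 10 of 16 genes had a lower diet response in mutants (median log2 -0.17, camera adjusted p = 0.261 for both).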

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

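The tests of list length, signal over background, sex, sample labels, library batch and rank in this part were chosen after the results were seen, and the test of linkage to Foxc1 was set beforehand. Libraries were compared within their group on 23 measures. Of 80 group comparisons 5 held a library set apart by more than the 95% critical value of Dixon's gap test, where chance gives about 4.

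Mutant 4 had 49804 deposited summits, against 108298 in the next lowest mutant. Mutant 6 on the diet had 36.2% of its matched summits within 1 kb of a gene end, against 32.1% in the next highest of its group. Mutant 4 on the diet had a median score of 7.33, against 11.1 in the next lowest. In the Wnt and BMP list, mutant 1 had 88 matched summits, against 78 in the next highest mutant, and control 1 on the diet had 75, against 83 in the next lowest of its group. Fgfbp3 stood out because its response to the diet differed between genotypes, with an interaction of 0.74 on the log2 scale.

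Sets of separated regions that differed in libraries outside their definition were those absent in mutants, and those gained or lost on the diet in mutants. Their differences at equal log2 list length were -14.2, 30.9 and -15.7 points (exact permutation p = 0.00866, 0.0317 and 0.0317). At equal median score, a measure of signal over background, they were -12.5, 33.2 and -18.2 points (exact permutation p = 0.0238, 0.00794 and 0.0397). Each kept its direction with 1 covariate fitted at a time, though the sets gained and lost on the diet in mutants shrank from 37.3 and -25.0 points. Labels were rearranged without regard to the covariate, and covariates were not fitted together, so a part played by either is not excluded. Sex was inferred from summits on chromosome Y, which 6 of 11 libraries on the diet and 1 of 8 off it had. At equal sex, tested with the same limits, the differences were -14.2, 27.0 and -19.7 points (exact permutation p = 0.0130, 0.0159 and 0.0159). Regions with an unadjusted genotype p under 0.05 were not concentrated near Foxc1: 10 of 751 (1.33%) lay within 20 Mb of it against 1.66% of all regions (Fisher's exact p = 0.5655). A linked haplotype predicted a higher share there. Since 11 of 100 splits of the libraries reached as many regions, chance cannot be excluded for this set, and the test cannot exclude a linked haplotype. An unrecorded batch that follows the diet stays open, because the labels name no batch. An effect of the diet shared by both genotypes may be a biological source of the differences of 30.9 and -15.7 points, as a hypothesis found and tested on the same data.

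Mutants 3 and 4 resembled libraries on the diet, with 64% and 65% of the regions gained on the diet in controls, against 18% and 20% in mutants 1 and 2, although over all regions they correlated with controls on the diet at 0.404 and 0.398, below the 0.496 and 0.530 of mutants 1 and 2 (with controls, 0.327 and 0.337 against 0.598 and 0.672). A difference in list length does not account for mutant 3, whose 108407 summits match the 108298 of mutant 1, but for mutant 4, with 49804, it cannot be told apart, since the 2 mutants on the diet of that length had shares on both sides (30% in mutant 6 with 48323 and 75% in mutant 5 with 52848). Signal over background cannot be told apart, since median scores were 8.19 and 6.44 in mutants 3 and 4 against 15.5 and 18.4 in mutants 1 and 2, no other library off the diet scored as low, and within mutants on the diet score and share correlated at 0.466 (exact permutation p = 0.272). Mislabelled samples could account for part of the pattern and cannot be told apart either, with 1 mutant on the diet, mutant 6, closest to mutant 1 (correlation 0.594), nor can an unlabelled batch, for which a split joining controls 1 and 2 with mutants 3 and 4 separated 628 regions against 68 for genotype, while controls 1 and 2 correlated with mutants 3 and 4 at 0.343 and with controls 3 and 4 at 0.566. Variable severity among mutants was not tested, and mutant 2, which has the mutant label, resembled controls as mutant 1 with the wild-type label did.

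Fgfbp3, whose protein binds fibroblast growth factors, gained a summit through a region present in the matched set of 6 of 6 mutants on the diet and 0 of 13 other libraries. If rank alone set this apart, most other libraries would have a weaker summit there, and 10 of 13 did. With the shortest list left out, which keeps 48323 summits per library, the interaction was 0.47 on the log2 scale (limma adjusted p = 0.980). A shift in rank is a candidate explanation, in line with the 10 libraries, and whether the region is more open in mutants on the diet was not tested, since read counts were not analysed here.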

How the results depend on the processing

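Tests chosen after seeing the data were those without mutants 3 and 4 together, with sex as covariate, without the robust step, with covariates in the checks of separated regions, and the alternatives of those checks. The stratified exact tests and Fisher's exact test called 0 regions under each alternative run, which shows no stability, since neither passes a few fully separated regions. Over all settings, the main results kept their direction and side of the threshold or stayed within 1.5-fold in 708 comparisons, changed direction in 24, no longer passed in 8, newly passed in 9 and moved by more in 153. Named genes kept direction and side in 1839 and gene lists in 2944; 124 gene values no longer passed, 6 newly passed and 8 list values newly passed. Motif shares and their alternatives, and a paired test of regions, were not run. Where no cause is given, the cause was not tested. The rank limit bounds each count: summits outside a library's 29112 best do not enter it, though deposited ones were looked up for regions. Sites too weak to be deposited are unseen, and a change of 2-fold was often missed in simulations.

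With all deposited summits, separated regions numbered 129, 416, 286, 1278 and 39 (mutants against controls, controls on against off the diet, mutants on against off the diet, mutants on the diet against controls, and against controls on the diet), limma called 0 genes in the last 3 and in the interaction, and camera called 1 list between mutants and controls, radial glia (median log2 0.10, adjusted p = 0.0153). Near-end shares turned to 4.82, 6.59 and 3.99 points for mutants on the diet against mutants, controls and controls on the diet. The checks of regions in other libraries gave 0.74 for those gained and -11.2 for those lost in mutants, -36.0 for those lost on the diet in controls (exact permutation p = 0.0381) and -30.2 for those lost on the diet in mutants. Summits per gene were scaled by list length in this setting, which shifts its log2 differences where list lengths differ. Etaa1 turned to 0.24 between mutants on and off the diet with this scaling, and to 0.33 with the shortest list left out.

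With 14556 summits per library, separated regions numbered 33, 92, 32, 64 and 1, which fewer summits alone would lower. Limma then called 2 genes between controls on and off the diet, 1 between mutants on and off it, and 0 for mutants on the diet against controls, against controls on the diet and for the interaction. Near-end shares turned to -1.32 for mutants against controls and -0.44 for controls on against off the diet, and the check of regions lost in mutants gave -7.67. With the shortest list left out (48323 summits per library), separated regions numbered 125, 292, 177, 509 and 35, and limma called 1, 4, 11, 7 and 0 genes in the same order, 0 of them shared with the genes called at 29112 summits, as with 14556. The near-end share of mutants on the diet against controls turned to 0.13, and the check of regions lost on the diet in mutants gave -19.6. With summits joined within 100 bp, 13 regions separated mutants from controls on the diet, and within 500 bp the check of regions gained in mutants turned to 1.

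Gene assignment moved calls as follows, though gene bodies with 5 kb on both sides cannot count the Fgfbp3 region, 6689 bp from the gene end. With gene bodies and 5 kb on both sides, limma called 1 gene for mutants on against off the diet, 1 for mutants on the diet against controls, 0 against controls on the diet and 0 for the interaction, and camera called 2 lists for controls on against off the diet (Hedgehog and meningeal fibroblast) and 1 for the interaction (Hedgehog). With gene ends within 50 kb, limma called 1, 1 and 0 genes for mutants on against off the diet, mutants on the diet against controls and the interaction, and camera 1 list for controls on against off the diet (meningeal fibroblast, adjusted p = 0.00539). Without sex chromosomes limma called 1 gene for mutants on against off the diet. With a pseudocount of 1 it called 1 gene there and 1 for mutants on the diet against controls. With no filter it called 3, and with no robust step 2, for controls on against off the diet. With log2 list length as covariate it called 5 genes for mutants on against off the diet (Etaa1, Fgfbp3, Psapl1 and Smyd3 among them) and 1 for mutants on the diet against controls. With a replicate block it called 0 in each contrast, including the 4 that otherwise had calls, and the numbers do not pair these libraries. With sex as covariate it called 1 for mutants on against off the diet and 1 for mutants against controls on the diet. At equal median score the check of regions gained in mutants turned to 0.17.

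Without mutants 3 and 4, separated regions numbered 264 for mutants against controls and 860 for mutants on against off the diet, where fewer libraries have to differ. Limma then called 1 gene for mutants against controls (Isl2), 1 for controls on against off the diet, 12 for mutants on the diet against controls and 3 for the interaction. The checks of regions gained and lost on the diet in controls gave 49.8 and -55.6 (exact permutation p = 0.0357 each, the smallest that 6 against 2 libraries allow). Those 2 libraries were chosen by their values in these sets, so these differences are no evidence of an effect.

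Leaving out 1 library at a time gave these ranges. Differences in deposited summits ran from -10163 (without control 2) to 12016 (without mutant 4) for mutants against controls. They ran from -46802 (without mutant 4) to -24679 for mutants on against off the diet, and from -41773 (without control 2) to -26774 for mutants on the diet against controls. Near-end shares ran from -0.612 (without mutant 1) to 0.978 points for mutants against controls and from -0.186 (without control 3) to 1.10 for controls on against off the diet. They ran from -1.28 to 0.393 (without mutant 1) for mutants on against off the diet, from -1.07 to 0.549 (without control 2) for mutants on the diet against controls, and from -1.40 (without mutant 6 on the diet) to -0.196 against controls on the diet. Separated regions, which grow when fewer libraries have to differ, numbered 104 to 396 (without mutant 2), 227 to 415 (without control 1), 69 to 189 (without mutant 3), 197 to 530 and 13 to 45 (both without mutant 6 on the diet), in the order given for all deposited summits. The checks in other libraries ran from -8.65 to 4.62 for regions gained in mutants and from -15.2 to -8.32 (without control 2) for those lost in mutants. They ran from 20.5 to 36.5 (without mutant 6 on the diet, newly past the threshold) for regions gained on the diet in controls, and from -36.7 (without mutant 3, newly past it, as without mutant 4) to -14.6 for those lost. They ran from 23.3 (without mutant 2) to 45.3 for regions gained and from -32.4 (without mutant 3) to -14.8 (without mutant 2) for regions lost on the diet in mutants. Limma called 0 to 2 genes for mutants against controls and 0 to 2 for controls on against off the diet, both highest without control 3. It called 0 (without mutant 1) to 7 for mutants on against off the diet, 1 to 13 for mutants on the diet against controls, 1 to 4 against controls on the diet and 0 to 3 for the interaction, with 7, 13 and 3 all without mutant 6 on the diet. Camera called 0 to 1 list for controls on against off the diet and 0 to 1 for the interaction (Hedgehog, without control 1).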

Other observations

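Counts from other splits of the libraries, and the tests behind them, were chosen in part after the results were seen. The counts below compare each result with up to 100 splits of the same libraries into groups of the same sizes, the real split included. Shares were not adjusted over the contrasts.

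Mean correlation of region presence within a group was 0.607 in controls, 0.572 in controls on the diet, 0.482 in mutants on the diet and 0.403 in mutants. The mutants formed 2 pairs: mutants 1 and 2 correlated at 0.631, mutants 3 and 4 at 0.503, and the cross pairs at 0.30 to 0.344.

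Summits on chromosome Y, 4 to 6 per library, occurred in control 1, controls 1 to 4 on the diet and mutants 1 and 4 on the diet, and 0 occurred in the other 12 libraries. With sex inferred from these summits as covariate, chosen after seeing the data, Fgfbp3 was the 1 gene called by limma between mutants on and off the diet. Separated regions and the stratified region counts were not adjusted for sex.

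Where a real count is 0, each split gives at least as many, so the number of splits says nothing about chance. For summits per gene by limma this holds for mutants against controls (0 genes, 35 of 35 splits, highest other 19) and controls on against off the diet (0 genes, 100 of 100, highest other 2). For mutants on against off the diet, 20 of 100 splits reached 2 genes (highest other 122), and for mutants on the diet against controls 8 of 100 reached 3 (highest other 22), so chance cannot be excluded for these counts, which hold Etaa1 and Rad51c. Between mutants and controls on the diet, 4 of 100 reached 3 genes (highest other 8), so chance can be excluded at a share of 0.05 only for that count taken alone, and the interaction reached 1 gene in 18 of 100 (highest other 5), where it cannot. The 122 genes of another split, many times the real count, point to a structure of the samples. That split sets mutants 3 and 4 and mutants 4 and 6 on the diet, the 4 libraries of these 10 with the lowest median scores (6.44 to 11.1), against the other 6 (11.6 to 18.4). The same limit holds for gene lists by camera, with real counts of 0 in 35 or 100 splits and highest other counts of 1, 2, 3, 3, 2 and 2 in the order of the contrasts.

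For separated regions, 12 of 35 splits reached the 68 of mutants against controls (highest other 628) and 12 of 100 the 54 of mutants on against off the diet (highest other 195, a split that puts mutants 3 and 4 with mutants 1, 2, 3 and 5 on the diet), so chance cannot be excluded for these counts. For controls on against off the diet only the real split of 100 reached 180 (1 of 100, highest other 134), and for mutants on the diet against controls 2 of 100 reached 175 (highest other 284), so chance can be excluded at a share of 0.05 for each taken alone. Between mutants and controls on the diet, 36 of 100 reached 8 (highest other 66), so chance cannot be excluded. Region tests by Fisher's exact test and the stratified exact tests called 0 in the real split and in each of 35 or 100 splits (highest other 0), which again says nothing about chance. At an unadjusted p under 0.05, diet within genotype gave 1864 regions, reached only by the real split of 100 (highest other 1191), the smallest share possible here. Chance can thus be excluded at a share of 0.05 only for that count taken alone. List length and median score were not adjusted for in this count or in the counts of separated regions. Mean list length was lower on the diet in both genotypes (77804 against 98555 summits in controls, 63769 against 95379 in mutants). Excluding chance therefore does not set the diet apart from library quality. Genotype within diet gave 751, reached by 11 of 100 (highest other 1457), so chance cannot be excluded there.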
